A study of Arabidopsis thaliana with 48 samples.

How the data were processed

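Gene expression was measured on 48 arrays of *Arabidopsis thaliana* accession Col-0, a standard laboratory strain. Leaves 7 to 10 of rosette plants aged 29 to 34 days were sampled at 8 times, which were 6, 12, 18 and 24 h and 2, 3, 4 and 5 d after inoculation in a settling tower with the powdery mildew fungus *Erysiphe orontii* from cultures 10 days old. Uninfected plants had a mock treatment in such towers and were sampled at the same times, per the labels. Each of the 16 groups (8 times, infected or uninfected) held 3 arrays. The sample titles number 16 arrays as experiment 2 and 16 as experiment 3. The 16 arrays whose titles carry no number were taken as experiment 1, so that each of the 3 experiments holds 1 array of every group. Per the labels, every harvest fell at the middle of the light period, also at 6, 12 and 18 h, which would need different times of inoculation, and these are not given in the sources used here. Nothing beyond the experiment number says that the arrays came from separate plants or pools, so p-values measure the spread between these arrays, part of which may be technical.

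The deposited values are intensities of Affymetrix probe sets on a linear scale, computed with MAS5 per the submitters' processing notes. The version, settings and scaling target of MAS5 are not given in the sources used here. In the deposited values the mean between the percentiles 2 and 98 was 100.0 on every array, so the authors' values had been scaled array by array. MAS5 subtracts mismatch probes, which makes dim probe sets noisy, and a common trimmed mean fixes the average level, so that every difference reported here is relative to the rest of the array. Median intensity ranged from 33.2 to 41.3 over the arrays. The number of arrays per group limits the precision.

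Values were analysed as log2(intensity + 2.59), where 2.59 was the 10th percentile of all deposited intensities. Differences on this scale understate the change of dim probe sets. Of 22810 probe sets, 64 controls were set aside, and of the remaining 22746 a probe set was kept when it exceeded its own array's 40th percentile on at least 3 of the 48 arrays. This level lay between 18.2 and 29.2 and left 16152 probe sets. The platform annotation supplied for this work gave 13513 of the 22746 probe sets 1 gene and 503 several genes, and 8730 were not listed in it and stay unnamed here. Symbols were brought up to date by gene number through the RefSeq table of assembly TAIR10.1, where 77 of the probe sets with 1 gene found no match. The array files name no genome build, so no coordinates are printed. A gene with several probe sets was represented by the one with the highest mean intensity.

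All 48 arrays entered 1 linear model with 16 group means in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with empirical Bayes moderation along the mean-variance trend and 32 residual degrees of freedom. Fitting all groups together gave 1 shared estimate of spread per probe set, because a group holds only 3 arrays. Contrasts were infected minus uninfected at each time, their mean over all 8 times, their mean over the 4 times up to 24 h (called the hour phase here) and over the 4 times from 2 to 5 d (the day phase), the difference between the phases, and 5 d minus 6 h in uninfected plants. F tests asked whether the infection response varied over the 8 times, whether uninfected plants varied over time, and whether the mean response differed between the experiments. P-values are limma's, two-sided and adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Errors of log2 differences are standard errors (SE) of the fit, and errors of intensities are SD over 3 arrays. Contrasts over several times count the times of an experiment as independent, although there were only 3 experiments. Their SE, p-values and counts therefore do not measure the spread of the response between experiments.

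The fit without an experiment term was the planned one. Whether the experiment number pairs the arrays was then checked from the correlation of the deviations of the infected and uninfected array of one time and experiment from their group means. Over 24 such pairs it had a median of 0.32 (lowest 0.04, highest 0.55), and it exceeded 0.1 in 23. Where the titles give a number, they name it as that of an experiment which spans all groups, and it was therefore taken as a pairing, with the unnumbered arrays as experiment 1. The fit with the experiment as a block, with 30 residual degrees of freedom, is given beside a result where it changed a call or moved a count by over 1.5 times. No arrays were duplicates of each other. The highest correlation of log2 values within a group was 0.975, the lowest 0.933, and the highest between any arrays 0.981.

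Before the data were examined, 17 gene lists with 336 genes were fixed, together with the design, the rule for named genes and all settings given below except those named as added later. The annotation named 42 of the 336 genes, and 36 were tested. Lists with at least 3 tested members were compared with all other genes by camera (preset correlation 0.01), adjusted over the 4 such lists. These were pattern-triggered immunity (7 of 28 genes tested), ER protein folding and secretion (4 of 20), photosynthesis (8 of 42), and sugar transport and invertases (5 of 21). The 8 lists with 1 or 2 tested members are described by gene only, namely salicylic acid signalling, jasmonate, ethylene and ERF-branch defence, cell cycle and endoreduplication, circadian clock, heat shock, glutathione and redox, and markers of guard cells, epidermis, trichomes and vasculature. No gene was tested from the 5 lists on camalexin and indolic metabolism, powdery mildew resistance and susceptibility, cysteine-rich receptor-like kinases, senescence and the floral transition.

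The genes named are members of the fixed lists and, for each of 5 contrasts (mean of all times, hour phase, day phase, day minus hour phase, uninfected 5 d minus 6 h), the 12 with the highest and the 8 with the lowest log2 difference among probe sets that passed the threshold, had 1 annotated gene and moved the same way within each experiment. For single times the rule took 3 and 2, and for the difference between experiments the 5 smallest p-values. Exceptions are stated where they occur. Alternatives were the experiment as a fixed or random block, no offset or an offset of 11.04, quantile normalization, scaling to the 75th percentile, no filter, a filter at the median on 6 arrays, no variance trend, only the arrays of a time, leaving out each experiment, and for lists an estimated correlation and fry. After the data had been seen, covariates for RNA quality (the 3'/5' ratios of GAPDH and ubiquitin control probe sets), lists at 4 and 5 d, gene families by symbol, and infected plants at 5 d minus 6 h were added.

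The model was tested on simulated data with 18084 probe sets. Changes of 0.5, 1 and 2 were given to 67, 67 and 66 of them, equal at all times of the day phase, with independent normal noise. In the data the response grew with time and covered many more probe sets, so the shares below need not hold for it. For the day phase it recovered 61.2% of simulated log2 changes of 0.5, 89.6% of changes of 1 and 97.0% of changes of 2, with 3 false calls. For 5 d alone the shares were 11.9%, 59.7% and 83.3%, with 2 false calls.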

Results

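The data were 48 arrays of *Arabidopsis* leaves, infected with the powdery mildew *Erysiphe orontii* or mock-treated, with 3 arrays at each of 8 times per treatment. *E. orontii* is a fungus that grows on the leaf surface and feeds from epidermal cells. The series was labelled as a study of the response to this infection, and infected leaves were set against uninfected leaves of the same time.

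Averaged over the 8 times, the highest rise under the naming rule was that of AT1G26380, a berberine bridge enzyme-like oxidoreductase gene, at 2.81 ± 0.18 (log2, SE, 24 arrays per treatment), followed by its relative AT1G26420 at 2.01 ± 0.18 and by AT3G18250 at 1.95 ± 0.19. The place of AT1G26420 depended on the offset. It was at 3.35 with no offset and at 1.15 with the larger one, where AT3G18250 was at 1.43 and CHI at 1.54. CHI, a gene annotated as a chitinase, rose by 1.77 ± 0.15, the chitinase family gene AT2G43590 by 1.38 ± 0.17 and AT1G65500 by 1.48 ± 0.09. AT4G14090, which encodes an anthocyanin glucosyltransferase, fell by 1.97 ± 0.40, DFR (dihydroflavonol reductase) by 1.73 ± 0.31, CHIL (a chalcone isomerase-like protein) by 1.64 ± 0.21 and ORA47, an AP2/ERF transcription factor gene, by 1.49 ± 0.27. Of the ER protein folding and secretion list 3 of 4 genes rose, 4 when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 8.86e-06). CNX2, the remaining member, was at 0.20 ± 0.07 (adjusted p = 0.0640, and 0.0415 with the experiment as a block, 0.0384 after quantile normalization and 0.0463 with 75th percentile scaling). PDF1.2B, a plant defensin gene, rose by 0.89 ± 0.30 (adjusted p = 0.0412), but not without experiment 1 (0.74, adjusted p = 0.2406) or 3 (0.85, 0.1619), without a filter (0.0584) or with RNA quality covariates (0.0538), and its probe set is of a type that can also bind related sequences. In all, 2239 of 16152 probe sets changed, 951 higher and 1288 lower in infected leaves, and 3402 with the experiment as a block. Leaving out experiment 2 left 1235 and leaving out experiment 3 left 1084.

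In the day phase, from 2 to 5 d, AT1G26380 rose by 4.21 ± 0.26 (log2, SE, 12 arrays per treatment) and its relatives AT1G26420, AT1G26410 and AT1G26390 by 3.41 ± 0.26, 2.11 ± 0.23 and 2.08 ± 0.21. AT3G18250 rose by 3.38 ± 0.26, CHI by 3.03 ± 0.22, AT1G57630, a TIR domain gene, by 2.92 ± 0.24, and AT1G51890, a leucine-rich repeat receptor kinase gene, by 2.60 ± 0.16. AT4G16260, a family 17 glycosyl hydrolase gene (the family of the beta-1,3-glucanases), rose by 1.63, 2.35 and 2.63 in experiments 1, 2 and 3. On the lower side, the naming rule gave AT4G14090 (fell by 2.89 ± 0.56), UF3GT, an anthocyanin glycosyltransferase gene (fell by 2.58 ± 0.53), DFR (fell by 2.57 ± 0.44), CHIL (fell by 2.19 ± 0.29) and ORA47 (fell by 2.06 ± 0.38). Signals of AT4G14090 and UF3GT in infected leaves of this phase lay mostly under the filter level, as did several of those of DFR and CHIL. The size and order of these falls therefore depended on the offset. AT4G14090 was at -3.72 with no offset and at -2.10 with the larger one, where DFR was at -2.24. Among the rises AT1G26420 moved most with it, to 5.62 with no offset and 2.03 with the larger one. The adjusted p-values of these genes lay between 3.87e-15 for AT1G51890 and 0.0038 for AT4G16260. The remaining genes under the naming rule were AT1G22890, AT1G51920 and AT2G18690 (2.53, 2.44 and 2.35) and, among the lower ones, AT2G22880, AT2G28400 and AT4G29780 (-1.78, -1.66 and -1.62). In total 3324 probe sets changed, 1562 higher and 1762 lower. Without experiment 2 the count was 1707, and AT2G22880 was no longer past the threshold (adjusted p = 0.0726). Without experiment 3 it was 1623, and AT2G22880 (0.0906) and AT4G29780 (0.0660) were not.

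Genes of the ER protein folding and secretion list rose together in the day phase. All 4 tested members passed, also when adjusted over the list alone. ERDJ3B, a co-chaperone, rose by 1.14 ± 0.11, the calreticulin gene CRT1B by 1.09 ± 0.10, CNX2 by 0.57 ± 0.10 and SEC61A, part of the translocation channel, by 0.43 ± 0.06. Their median was 0.83 (camera adjusted p = 1.87e-08, and adjusted p = 5.23e-04 with an estimated correlation). Other members of this list, which had 20 genes, were not analysed here.

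The pattern-triggered immunity list was mixed in the day phase. Of 7 members WRKY6 (0.76 ± 0.16), the receptor-like cytoplasmic kinase gene BIK1 (0.62 ± 0.09) and the ubiquitin ligase gene PUB24 (0.36 ± 0.12) rose, and ZAT10, a zinc finger transcription factor gene, fell by 1.17 ± 0.39. These 4 also passed when adjusted over the list alone, and WRKY53, PUB23 and WRKY22 (0.58, 0.67 and 0.05) did not pass. As a list it was higher than other genes (median 0.58, camera adjusted p = 0.0223), but adjusted p = 0.2108 with an estimated correlation and adjusted p = 0.1370 without experiment 1. The list also missed the threshold under the stricter filter (adjusted p = 0.0984) and with RNA quality covariates (adjusted p = 0.0800). Without experiment 2 or 3, ZAT10 (adjusted p = 0.2587 and 0.3011) and PUB24 (0.1092 and 0.1595) did not pass.

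Sugar genes moved both ways in the day phase. CWINV6, annotated as a cell wall invertase, rose by 0.77 ± 0.15, while the vacuolar invertase gene BFRUCT3 fell by 0.80 ± 0.14 and SWEET11, a sucrose transporter gene, fell by 0.41 ± 0.11. SWEET2 and APL3 did not pass (0.19 and -0.25), and the same 3 genes passed when adjusted over the list alone. As a list, sugar transport and invertases did not differ from other genes (median -0.25, camera adjusted p = 0.4224). SWEET11 did not pass without experiment 2 (adjusted p = 0.0800) or 3 (0.1339). Of 8 photosynthesis genes only PSAN, a photosystem I subunit gene, fell in the day phase, by 0.19 ± 0.06, also when adjusted over the list alone, and it did not pass without experiment 1, 2 or 3 (adjusted p = 0.0522, 0.1659 and 0.1007). The list median was -0.03 (camera adjusted p = 0.3716).

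Of the lists with 1 or 2 tested genes, the jasmonate methyltransferase gene JMT fell by 0.64 ± 0.15 in the day phase (adjusted p = 0.0020), FAMA, a transcription factor gene of guard cells, fell by 0.41 ± 0.11 (adjusted p = 0.0046), and SAG101, a salicylic acid signalling gene, and NDB2, an alternative NADH dehydrogenase gene of the redox list, rose by 0.39 ± 0.14 and 0.29 ± 0.11 (adjusted p = 0.0435 and 0.0440). Each of these calls ended when single experiments were left out. Without experiment 3 the adjusted p-values were 0.0953 for JMT, 0.0515 for FAMA, 0.2563 for SAG101 and 0.0862 for NDB2, without experiment 2 they were 0.0761 for FAMA, 0.1258 for SAG101 and 0.7477 for NDB2, and without experiment 1 the value for SAG101 was 0.0793. The differences themselves were -0.54 for JMT without experiment 3, -0.40 and -0.37 for FAMA without experiment 2 and 3, 0.39, 0.42 and 0.35 for SAG101 without experiment 1, 2 and 3, and 0.10 and 0.38 for NDB2 without experiment 2 and 3. With all arrays, SAG101 (adjusted p = 0.0654) and NDB2 (0.0605) also missed the threshold without a filter, and NDB2 with RNA quality covariates (0.0883). GRX480 (0.32), PDF1.2A (0.35), PDF1.2B (0.97), SIM (-0.14), GI (-0.21), HSP22 (-0.05) and UPOX (-0.20) did not pass. MCM7, a replication licensing gene of the cell cycle list, was at 0.36 ± 0.15 (adjusted p = 0.1042, and 0.0135 with the experiment as a block).

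**Figure D1:**
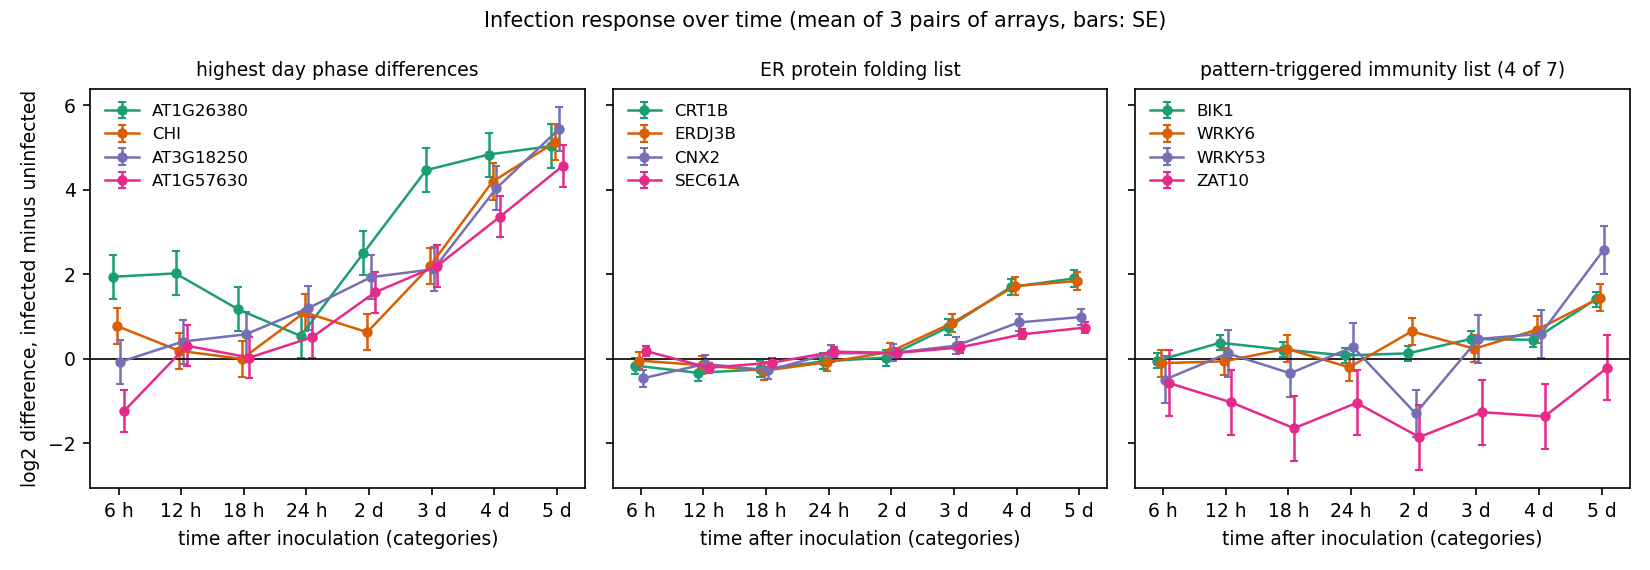
Log2 difference between infected and uninfected leaves (vertical axis) at each of the 8 times (horizontal axis, equally spaced categories) for 4 genes with high day phase differences, the 4 tested genes of the ER protein folding list and 4 of the 7 tested genes of the pattern-triggered immunity list. Points are means of 3 pairs of arrays and bars are SE; AT1G26380 reached 5.03 and CRT1B 1.90 at 5 d, while ZAT10 was at -0.21.

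The response grew from 3 to 5 d. At 3 d, AT1G26380 rose by 4.46 ± 0.52 (log2, SE, n = 3 per group), AT1G26420 by 3.48 ± 0.51 and AT1G22890 by 2.72 ± 0.39, and CHIL fell by 2.37 ± 0.59 and TBL26, a trichome birefringence-like gene, by 2.03 ± 0.31. At 4 d, AT1G26380 rose by 4.83 ± 0.52, CHI by 4.19 ± 0.43 and AT3G18250 by 4.03 ± 0.52, while AT4G14090 fell by 3.76 ± 1.12 and UF3GT by 3.57 ± 1.06. At 5 d, AT3G18250 rose by 5.43 ± 0.52, CHI by 5.12 ± 0.43 and AT1G26380 by 5.03 ± 0.52, while AT4G14090 fell by 3.86 ± 1.12 and DFR by 3.41 ± 0.89. Mean intensity of CHI at 5 d was 1033 ± 189.7 in infected and 28.7 ± 13 in uninfected leaves (SD, n = 3), and that of DFR was 36.5 ± 30.7 and 403 ± 291. The number of changed probe sets was 170 at 3 d (87 higher, 83 lower), 976 at 4 d (487 higher, 489 lower) and 2939 at 5 d (1360 higher, 1579 lower), and with the experiment as a block 436 at 3 d and 1974 at 4 d. Without experiment 1, 2 or 3 the count at 3 d was 59, 42 and 28. Without experiment 2 it was 303 at 4 d and 874 at 5 d, and without experiment 3 it was 149 and 1060. CHIL at 3 d lost its call without any one experiment (adjusted p = 0.0627, 0.2843 and 0.3666 without experiment 1, 2 and 3) and with no offset (0.0548). AT4G14090 and UF3GT lost theirs at 4 d without experiment 2 (adjusted p = 0.1552 and 0.0968) or 3 (0.4261 and 0.4557) and after quantile normalization (-3.53 and -3.44, adjusted p = 0.0622 and 0.0520) or when fitted to the arrays of 4 d alone (0.1709 and 0.1803), AT4G14090 also with no offset (0.0579), and UF3GT without a filter (0.0514) or with RNA quality covariates (0.0745). At 5 d AT4G14090 lost its call without experiment 1 (0.0924) or 3 (0.1794) and DFR without experiment 3 (0.1791).

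**Figure D2:**
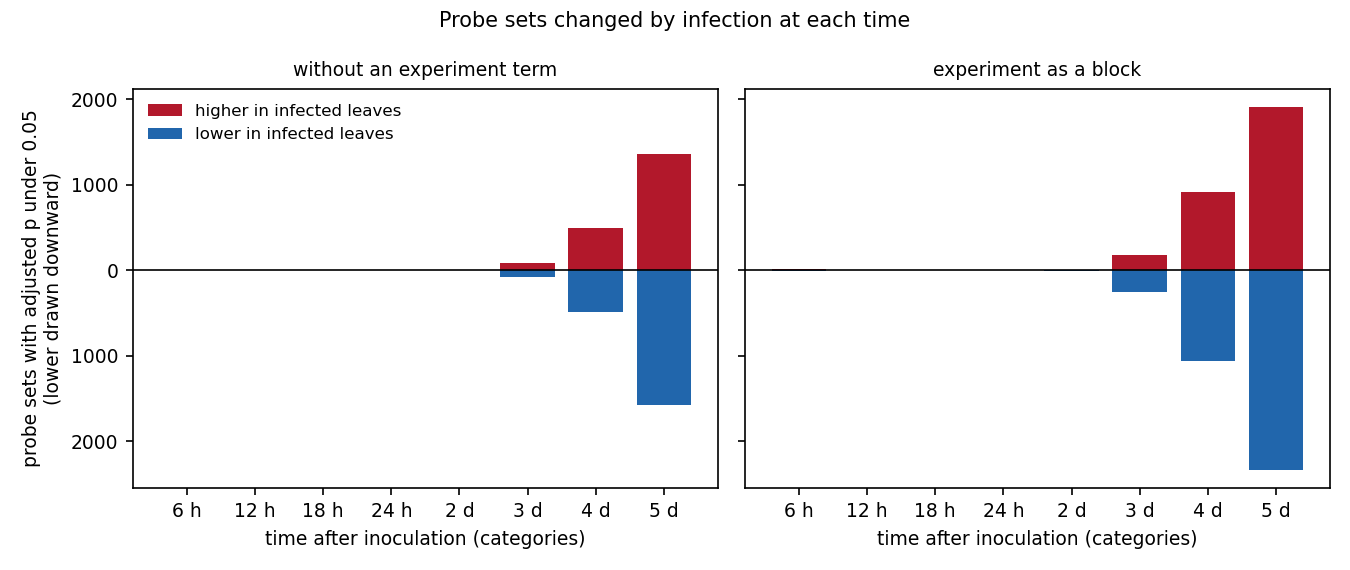
Number of probe sets with an adjusted p under 0.05 at each time (horizontal axis, equally spaced categories), higher in infected leaves drawn upward and lower drawn downward, without an experiment term and with the experiment as a block. Bars rise from 170 probe sets in total at 3 d to 2939 at 5 d without the term.

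Among the lists at 5 d, tested there after the day phase had been seen, the pattern-triggered immunity genes PUB23 (2.70 ± 0.69), WRKY53 (2.57 ± 0.56), WRKY6 (1.44 ± 0.32), BIK1 (1.41 ± 0.18) and PUB24 (0.79 ± 0.23) rose, 5 of 7, also when adjusted over the list alone (camera adjusted p = 4.25e-05, and adjusted p = 0.0176 with an estimated correlation). PUB23 and WRKY53 lost the call without experiment 3 (adjusted p = 0.1076 and 0.0584), and PUB24 without experiment 2 (0.1277) or 3 (0.1039). All 4 ER genes rose at 5 d, led by CRT1B at 1.90 ± 0.19 and ERDJ3B at 1.84 ± 0.21, with a median of 1.41 (camera adjusted p = 4.48e-08), and at 4 d their median was 1.28 (camera adjusted p = 1.49e-10). CNX2 was the member that missed the threshold at 5 d without experiment 2 (adjusted p = 0.0794). Of 8 photosynthesis genes, PSAN (fell by 0.66 ± 0.12), LHCB4.2 (fell by 0.45 ± 0.13) and PSBW (fell by 0.33 ± 0.12) fell at 5 d, 4 when adjusted over the list alone and 6 with the experiment as a block, where LHCB4.1 (-0.30, adjusted p = 0.0479), PRK (-0.29, 0.0255) and SBPASE (-0.40, 0.0221) also passed. The list was lower than other genes (median -0.32, camera adjusted p = 0.0012), but not with an estimated correlation (adjusted p = 0.2124). Without experiment 1, 2 or 3, LHCB4.2 did not pass (adjusted p = 0.10, 0.0675 and 0.0969) and neither did PSBW (0.2622, 0.1040 and 0.2223). PSBW also missed the threshold after quantile normalization (adjusted p = 0.3169) and 75th percentile scaling (0.0718), with no offset (0.0512), without a filter (0.1108) or the variance trend (0.0610), with RNA quality covariates (0.0902) and, as did LHCB4.2 (0.1581), when fitted to the arrays of 5 d alone (0.2764), and the photosynthesis median was -0.13 after quantile normalization (camera adjusted p = 0.0447). The sugar list held a median of 0.05 at 5 d, with a camera direction below 0 (adjusted p = 0.9898). SIM, a cell cycle inhibitor gene of endoreduplication, fell by 0.84 ± 0.16 at 5 d (adjusted p = 2.24e-04). With the experiment as a block MCM7 (0.77, adjusted p = 0.0087), SWEET11 (-0.46, 0.0478) and FAMA (-0.53, 0.0441) also passed at 5 d, and BIK1 (0.45, 0.0424) and CWINV6 (0.89, 0.0448) at 4 d.

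Before 3 d few probe sets changed at any single time. At 6 h 2 probe sets that the annotation does not name rose by 2.28 ± 0.39 and 2.16 ± 0.39 (n = 3 per group, limma adjusted p = 0.0170 and 0.0227), and at 2 d 1 unnamed probe set fell by 2.06 ± 0.37 (adjusted p = 0.0394). All 3 were chosen after their values were seen. AT1G26380, which rose later, was at 1.94 ± 0.52 at 6 h (adjusted p = 0.2801) and at 2.50 ± 0.52 at 2 d (adjusted p = 0.0889), and its mean intensity at 6 h was 17.1 ± 6.97 in infected and 2.71 ± 2.52 in uninfected leaves (SD, n = 3). The counts were 2 at 6 h and 1 at 2 d, and with the experiment as a block 28 and 7. At 6 h the count was 0 without experiment 1 or 3 and 1 without experiment 2, and at 2 d it was 0 without experiment 1 or 3 and 4 without experiment 2. At 12, 18 and 24 h limma gave 0, with 653, 813 and 661 probe sets at an unadjusted p under 0.05, and with the experiment as a block 5, 1 and 3 passed. These unadjusted counts were near or below a share of 0.05 of the 16152 probe sets, which would be reached without any difference. Without experiment 2 the count at 12 h was 1, and without experiment 1 the count at 18 h was 2.

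Averaging the 4 times of the hour phase gave 270 calls, but only 8 without experiment 3. AT1G26380 rose by 1.42 ± 0.26 (log2, SE, 12 arrays per treatment, adjusted p = 0.0019), EXO, a gene of brassinosteroid-promoted growth, by 1.37 ± 0.23, AT1G22890 by 1.29 ± 0.19 and CML30, a calmodulin-like gene, by 0.93 ± 0.22. TBL26 fell by 0.97 ± 0.16, AT4G27657 by 1.17 ± 0.27, CHIL by 1.09 ± 0.29, the flavonol rhamnosyltransferase gene UGT78D1 by 0.77 ± 0.14 and AT1G06000, a flavonol 7-O-rhamnosyltransferase gene, by 0.89 ± 0.19. Other genes under the naming rule were AT3G62950 (1.33), AT1G07050 (1.29), AT3G51720 (1.19), AT4G33980 (1.16), AT3G15450 (1.04), AT5G62360 (0.97), AT3G52480 (0.96) and AT1G02360 (0.91) on the higher side, and AT1G66440 (-1.01), AT3G62820 (-0.88) and AT5G19580 (-0.83) on the lower. None of the 4 tested lists and none of their members passed over all genes in limma, and adjusted over the list alone 2 sugar genes passed. For the ER list the median was -0.16 (camera adjusted p = 0.2642), for pattern-triggered immunity -0.09 (0.7296), for photosynthesis 0.01 (0.6298) and for sugar genes -0.05 (0.2642). With the experiment as a block SWEET11 (-0.31, adjusted p = 0.0274), APL3 (-0.51, adjusted p = 0.0184) and ZAT10 (-1.07, adjusted p = 0.0474) passed.

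In the hour phase 270 probe sets changed, 120 higher and 150 lower (142 and 140 with 75th percentile scaling), and 813 with the experiment as a block. The experiments contributed unequally. Tested within 1 experiment at a time, experiment 3 gave 1821 probe sets, experiment 1 gave 42 and experiment 2 gave 0 (1284 at an unadjusted p under 0.05). Each such fit had 8 arrays, 1 per time and treatment, so that the times stood in for replicates and the counts do not measure the spread between plants. Without experiment 2 the count was 67 and without experiment 3 it was 8. Of the 20 genes named for this phase, 11, 5 and 3 kept their call without experiment 1, 2 and 3, AT1G26380 having an adjusted p of 0.3297 without experiment 3. After quantile normalization CHIL (adjusted p = 0.0708), AT5G62360 (0.0591) and AT1G66440 (0.0556) did not pass. CHIL and AT3G62950 also did not pass with no offset (0.0692 and 0.0514), without a filter (0.0647 and 0.0603) or without the variance trend (0.0559 and 0.0537), nor AT5G62360 without a filter (0.0557) or the trend (0.0509), nor AT1G66440 without a filter (0.0541) or with the larger offset (0.0595). In the day phase the counts within experiments 1, 2 and 3 were 346, 69 and 102.

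**Figure D3:**
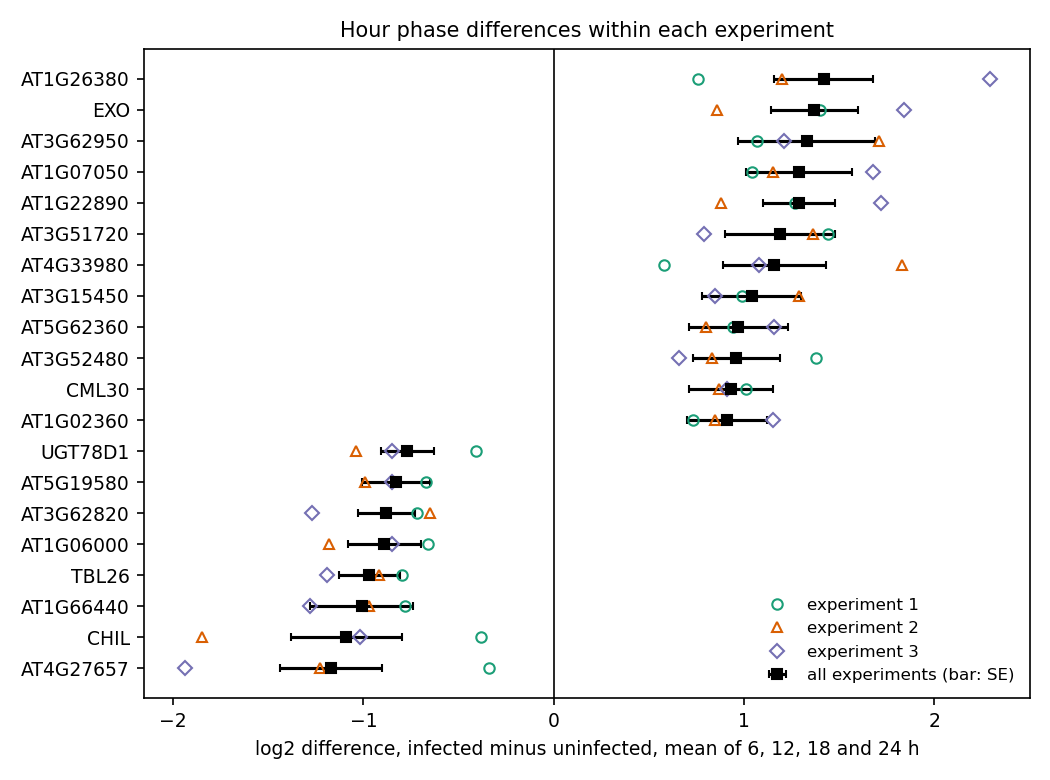
Log2 difference between infected and uninfected leaves, averaged over 6, 12, 18 and 24 h (horizontal axis), for the 20 genes named for the hour phase (vertical axis). Black squares are the fit to all experiments with SE bars and open symbols are the single experiments; EXO was at 1.40, 0.86 and 1.84 in experiments 1, 2 and 3.

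The hour and day phases rest on different arrays, and 139 of the 270 hour phase probe sets also changed in the day phase. Of these, 32 were higher in both (11.6 expected for independent lists) and 102 were lower in both (16.4 expected). The expected numbers are a rough guide, because both calls use the same estimate of spread per probe set, which can place a probe set on both lists. That alone would not favour the same direction, and the opposite directions given below had 13.1 and 14.5 expected. Both phases come from the same 3 experiments, however. A lasting difference between infected and mock-treated plants of an experiment could favour the same direction, and this was not tested. TBL26, CHIL and AT1G22890 were among the genes that moved the same way in both phases. Only 3 were higher in the hour phase and lower in the day phase, and 2 the reverse, among them AT4G32340 (0.52 in the hour phase, -0.34 in the day phase) and PPR336 (-0.35 and 0.32), both named after their values were seen.

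A direct test of the day phase against the hour phase asked whether the response differed between the periods. It was higher in the day phase by 3.01 ± 0.34 for AT1G57630 (log2, SE, adjusted p = 1.38e-07), by 2.85 ± 0.37 for AT3G18250, by 2.52 ± 0.31 for CHI and, in experiments 1, 2 and 3, by 1.85, 2.23 and 2.52 for AT1G51890. The response of AT3G51720 was lower in the day phase (-2.00, -1.63 and -0.88 in experiments 1, 2 and 3, adjusted p = 0.0180), as were those of AT1G62510 and AT1G57590 (both -1.37) and AT1G51090 (-1.36). The other genes under the rule were AT1G26420 (2.82), AT1G26380 (2.79), AT1G68620 (2.19), AT5G55450 (2.08), AT5G55420 (2.04), AT1G51920 (2.00), AT1G26390 and AT1G26410 (both 1.95), and AT1G20030 (-1.37), AT2G38465 and AT4G33980 (both -1.26) and AT2G28400 (-1.22). All 4 ER genes had a higher response in the day phase, adjusted over all genes and over the list alone, among them CRT1B (adjusted p = 3.70e-08) and ERDJ3B (1.28 ± 0.15), with a median of 1.02 (camera adjusted p = 7.47e-10). CNX2 (0.75) did not pass without experiment 2 or 3 (adjusted p = 0.0562 and 0.1334), nor SEC61A (0.42) without experiment 3 (0.0903). In the pattern-triggered immunity list WRKY6 (0.79 ± 0.22) and BIK1 (0.46 ± 0.12) were higher, 2 of 7, and 3 adjusted over the list alone (camera adjusted p = 0.0155, but adjusted p = 0.1800 with an estimated correlation and adjusted p = 0.0644 without experiment 1, 0.0738 under the stricter filter and 0.0505 with RNA quality covariates). BIK1 did not pass without experiment 1, 2 or 3 (adjusted p = 0.0964, 0.1614 and 0.0905), nor WRKY6 without experiment 2 or 3 (0.1998 and 0.1733). With the experiment as a block SAG101 (0.49, adjusted p = 0.0449) and the clock gene GI (-0.48, 0.0262) also passed.

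Between the phases 1488 probe sets differed, 848 with a higher and 640 with a lower response in the day phase, and 2892 with the experiment as a block. Without experiment 2 the count was 283 and without experiment 3 it was 247, and 19, 10 and 12 of the 20 named genes kept their call without experiment 1, 2 and 3. AT3G51720 lost its call without experiment 1, 2 or 3 (adjusted p = 0.0518, 0.2432 and 0.0609). The F test over all 8 times found 588 probe sets whose response varied, 1876 with the experiment as a block, 60 without experiment 2 and 85 without experiment 3.

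Uninfected leaves also changed with time, which bears on any comparison of a late infected sample with an early one. From 6 h to 5 d, AT4G14090 rose by 3.95 ± 1.12 (log2, SE, n = 3 per group, limma adjusted p = 0.0261), DFR by 3.55 ± 0.89, AT3G53980 by 3.07 ± 0.68, SUFE2 by 2.71 ± 0.54, the linker histone gene HIS1-3 by 2.37 ± 0.52 and GAMMA-VPE, a vacuolar processing enzyme gene, by 1.95 ± 0.49. AT1G13650 fell by 3.40 ± 0.75, AT3G16670 by 3.10 ± 0.64 and AT5G15780 by 2.77 ± 0.84. Also named under the rule were AT2G17710 (2.62), AT4G14900 (2.09), AT1G64360 (2.08), AT3G09020 and AT1G21000 (both 2.01), BPEp (1.99), AT2G22200 (-2.34), AT1G60590 and AT2G20670 (both -2.25), AT3G53250 (-2.06) and AT2G34620 (-1.96). Of the fixed lists, SBPASE, a Calvin cycle gene, fell by 0.72 ± 0.17, MCM7 by 1.11 ± 0.31 and SWEET2 by 1.54 ± 0.42. Without experiment 3 these had adjusted p-values of 0.1963, 0.2952 and 0.2630, and SBPASE and SWEET2 also missed the threshold without experiment 1 (0.0517 and 0.2108) and MCM7 without experiment 2 (0.0688). With the experiment as a block ATPC1 (-0.28, adjusted p = 0.0316), PRK (-0.27, 0.0474) and HSP22 (-1.08, 0.0296) also passed.

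The uninfected contrast held 1454 probe sets, 796 higher and 658 lower at 5 d, and 3506 with the experiment as a block. Scaling to the 75th percentile gave 1417, with 527 higher and 890 lower, and quantile normalization 1488, with 737 higher and 751 lower, so the balance of directions depended on the scaling. With the RNA quality covariates 950 of the 1454 stayed past the threshold and without a filter 973. The covariates ended the calls of AT1G64360 (adjusted p = 0.0878), AT5G15780 (0.0762), AT2G20670 (0.0799) and SWEET2 (0.0539). AT1G64360 also missed the threshold without a filter (0.0513), AT4G14090 with no offset (0.0539) and AT5G15780 with the larger offset (0.0591) and after quantile normalization (0.0585). Without experiment 1, 2 or 3 the count was 402, 904 and 11, and 9, 17 and 0 of the 20 named genes kept their call, AT4G14090 having an adjusted p of 0.3086 without experiment 3. Over all 8 times 1507 probe sets varied in uninfected leaves, 3906 with the experiment as a block, 932 without experiment 1, 348 without experiment 2, 11 without experiment 3, and 730 with the RNA quality covariates added after the data had been seen.

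**Figure D4:**
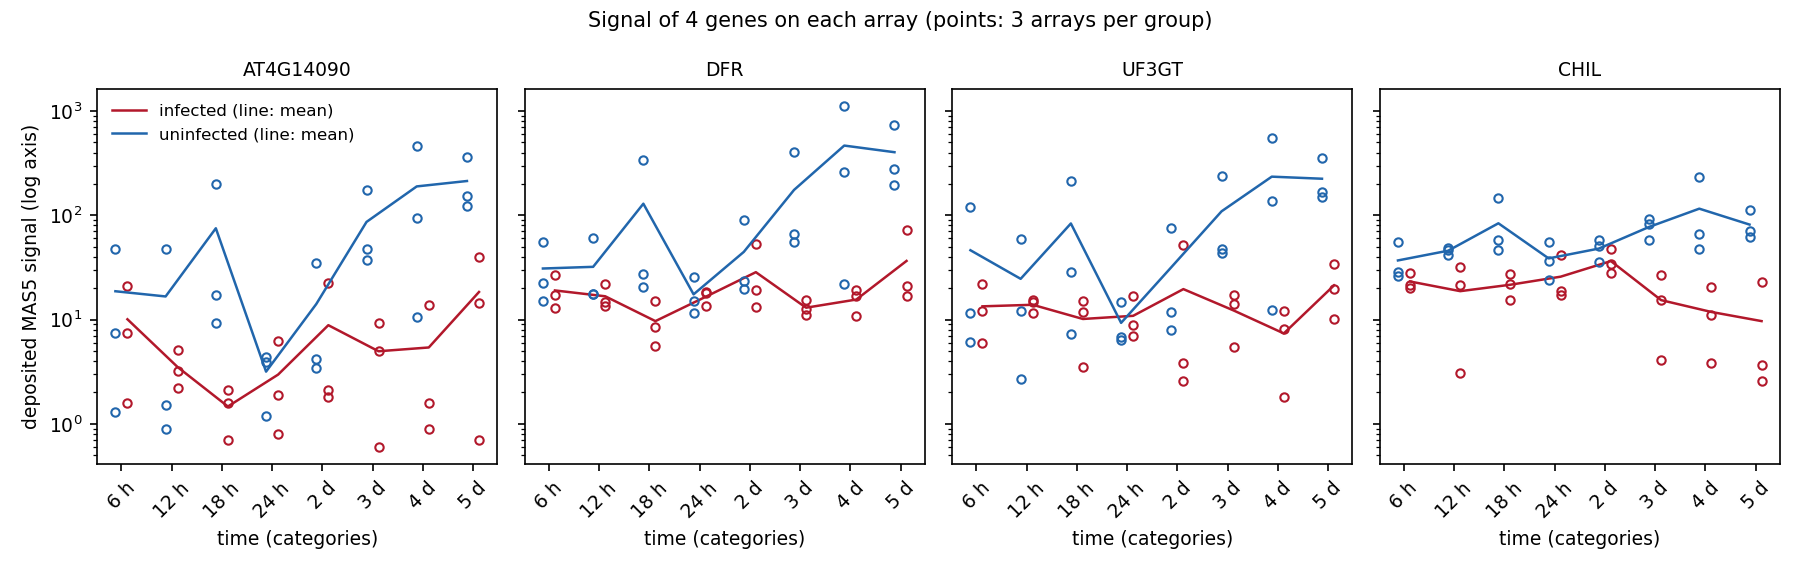
Deposited MAS5 intensity (vertical axis, log scale) of AT4G14090, DFR, UF3GT and CHIL on each array at each time (horizontal axis, equally spaced categories). Points are the 3 arrays per group and lines their means; at 5 d the mean for DFR was 403 in uninfected and 36.5 in infected leaves.

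The experiments were compared for their mean infection response. It differed for AT1G20070 alone (limma adjusted p = 0.0047), with a difference of -0.26 in experiment 1, 0.65 in experiment 2 and 0.61 in experiment 3, and 1816 probe sets had an unadjusted p under 0.05. The next smallest p-values belonged to AT1G04770 and AT1G36310 (both adjusted p = 0.0750, AT1G04770 passing with RNA quality covariates at 0.0487), AT4G27657 and AT1G16260 (both 0.1077). Fitted to pairs of experiments, the count was 0 without experiment 1, 20 without experiment 2 and 2 without experiment 3.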

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

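The tests of falling probe sets against fungal RNA, of single experiments and of the change with time for AT4G14090, DFR, UF3GT and CHIL, and of RNA quality were chosen after the results they bear on had been seen.

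The response of AT1G26380, CHI and the ER genes was stronger in the day than in the hour phase, and 1488 probe sets differed between the phases. Of these, 93.7% passed with the same sign after quantile normalization and 96.0% with the 3'/5' ratios as covariates, so most did not depend on these choices. Quantile normalization, like the authors' scaling, gives all arrays a common level, so it cannot test that assumption. The ratios were those of GAPDH and ubiquitin only, and GAPDH was itself higher in infected leaves in the day phase. Other aspects of RNA quality were not tested. RNA of the growing fungus, which may bind plant probe sets, stays open. The 43.0% with a lower response do not decide it, because MAS5 subtracts mismatch probes and scales each array to a common mean, so that foreign RNA can also lower a value. Of the higher ones, 6.0% (51 of 848) were at or below the filter level on all 12 uninfected day phase arrays against 2.8% of all tested probe sets, although plant genes switched on by infection would look alike. A plant response that grows with the infection also remains, as a hypothesis.

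In the hour phase, experiment 3 alone gave 1821 probe sets, and a difference confined to that experiment could be the source of much of its response. Of those 1821, 63.8% had the same sign in the mean of experiments 1 and 2 (56.5% in experiment 1 alone and 68.5% in experiment 2 alone), against 52.8% of all tested probe sets. The 63.8% lay between cut-offs chosen beforehand for such a difference and for a common response. The shares that either would leave were not measured. In the direction of experiment 3, their median difference was 0.07 in the mean of experiments 1 and 2, against a median size of 0.49 in experiment 3. The explanations cannot be told apart for those probe sets, since 1 array per group and experiment leaves the sign of small differences uncertain. Of the 270 found over all experiments, 91.1% passed with the same sign after quantile normalization, so most did not depend on the choice between these scalings. An early plant response stays open too.

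AT4G14090, DFR, UF3GT and CHIL, whose products act in the flavonoid pathway, were lower in infected leaves. Each gene passed the threshold in the day phase whichever experiment was left out (12 of 12 combinations), so the calls did not hang on 1 experiment. The highest adjusted p in limma was 0.0367, for UF3GT without experiment 3, at -2.27. The naming rule, applied to the same arrays, had already required a call and the same direction within each experiment. The direction therefore tested nothing, and the calls are not independent of that choice. A candidate explanation is a rise with time in uninfected leaves that infected leaves lacked. The median change from 6 h to 5 d was 0.50 in infected leaves, with no gene past the threshold, and 3.32 in uninfected leaves, where AT4G14090 and DFR passed. Without experiment 3 neither passed (limma adjusted p = 0.3086 and 0.2836). In experiment 2 the uninfected signals did not rise steadily. Those of AT4G14090 and DFR were 199.0 and 340.2 at 18 h, 3.9 and 11.6 at 24 h, and 154.6 and 280.1 at 5 d. UF3GT and CHIL were also higher at 18 h than at 5 d there. CHIL was at -1.45 ± 0.59 in infected leaves (limma adjusted p = 0.0586) and at 1.12 ± 0.59 in uninfected leaves (adjusted p = 0.2200), neither past the threshold. The uninfected arrays at 5 d enter both the fall with infection, for which these genes were named, and the rise with time. A larger change in uninfected leaves was therefore partly fixed in advance. Whether the rise came from the handling of the mock-treated plants was not tested.

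The F test over the 8 times gave 588 probe sets with a varying response, a difference between time points. The mean response of 1 probe set, AT1G20070, differed between the experiments (adjusted p = 0.0047). Among control probe sets, which were set aside except for the RNA quality covariates, 4 of the 5 for GAPDH, a glycolytic gene often taken as constant, were higher in infected leaves in the day phase, the 5 lying between 0.28 and 0.43. All 5 passed with the experiment as a block (the highest adjusted p in limma going from 0.2149 to 0.0027), and at 5 d all 5 were higher (0.70 to 0.97). The 45 spike-in probe sets had medians of 0.01 in the day phase and -0.03 at 5 d, with none past the threshold. Single spike-in probe sets ranged from -0.46 to 0.28 in the day phase and from -0.59 to 0.52 at 5 d.

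Exchanging infected and uninfected arrays within each time, in 100 splits with the real one, excluded chance for the mean of all times (2239, highest other 253), the hour phase (270, highest other 38), the day phase (3324, highest other 1824), the difference between the phases (1488, highest other 795) and, by 3 splits of 100, the variation over 8 times (588, highest other 1251). Exchanging within pairs of one time and experiment, which parts as many pairs as the real split, also excluded it for the first 4 (highest others 1151, 0, 2658 and 833) and did not for the variation over times, where 8 splits of 100 gave at least 588 (highest other 1272). The 7 others among these kept all 3 pairs of 5 d on one side, as 31 of the 99 other splits did, so that they hold the 5 d response with or without its sign. Chance here means a random assignment of single arrays or pairs, because both exchanges treated the times of an experiment as independent. A lasting difference between infected and mock-treated plants of an experiment, from a source other than infection, would also set the real split apart. The exchanges cannot exclude it. Of the 4 tested lists, only the 2 that had passed camera in the day phase were split, with no adjustment for that choice. The measure was the distance of the list median from 0, not from other genes. For the ER list (0.83), 1 split of 100, the real one, was as far in each exchange (highest other 0.64 within each time and 0.79 within pairs), which excluded chance. For the pattern-triggered immunity list (0.58) the margin was narrow, with 1 split when exchanging within each time (highest other 0.56) and 2 within pairs (highest other 0.61). Chance was not excluded for the number of list calls (5, highest other 9 in both), which 16 and 36 splits of 100 reached. It was excluded for variation over time in uninfected leaves, when times were exchanged among all 24 uninfected arrays (1507, highest other 1749, 2 splits of 100) and within each experiment (highest other 117, 1 split of 100), and not for the difference between experiments (1, highest other 328, 5 splits of 100), where a split with so many may come from a structure of the samples, which was not tested.

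For single times, 10 splits of 6 arrays are too few for a share under 0.05. The real and highest other values were 2 and 0 at 6 h, 0 and 0 at 12 h and at 18 h (all 10 splits gave 0), and 0 and 1 at 24 h. At 12, 18 and 24 h the real split had 653, 813 and 661 probe sets at an unadjusted p under 0.05 in limma. These counts were near or below the share of 0.05 expected without any difference. The real and highest other values were 1 and 1 at 2 d, 170 and 0 at 3 d, 976 and 8 at 4 d, and 2939 and 11 at 5 d. For uninfected leaves, 5 d against 6 h, they were 1454 and 3.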

How the results depend on the processing

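The RNA quality covariates were chosen after the data had been seen, and all other settings before the data were examined. No call of a named gene or a list reversed its direction. The balance of higher and lower probe sets did change, in uninfected leaves at 5 d minus 6 h under both other scalings and without experiment 3, in the hour phase with 75th percentile scaling, in the day phase without experiment 3, at 5 d when fitted to its arrays alone, at 6 h with either block, and at 3 and 4 d, where both directions were nearly equal, under several settings. The pattern-triggered immunity median in the hour phase, which was not past the threshold, went from -0.09 to 0.01 after quantile normalization. Of 183 calls for named genes, 177 stayed with no offset, 181 with the larger offset, 174 after quantile normalization (which also ended the calls of AT4G33980 between the phases, 0.0587, AT5G15780 in uninfected leaves, 0.0585, and CRT1B at 3 d, 0.0573, as adjusted p), 182 with 75th percentile scaling, 170 without a filter, 178 without the variance trend, 173 with RNA quality covariates, and 145, 119 and 90 without experiment 1, 2 and 3. Counts for the mean of all times, the hour, day and difference contrasts stayed within 1.5 times under both scalings, both offsets, both filters, no trend and RNA quality covariates. Background limits dim probe sets, and fewer arrays can leave fewer calls, but the cause of the changes below was not tested.

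With the experiment as a block the counts were 28, 5, 1, 3 and 7 at 6, 12, 18, 24 h and 2 d, 436 at 3 d, 1974 at 4 d, 3402 over all times, 813 in the hour phase, 2892 between the phases, 3506 in uninfected leaves at 5 d minus 6 h, 1876 for the variation of the response and 3906 for uninfected leaves over time. All probe sets called without the block were called with it, and beyond 18 further calls for named genes the block changed no other call of a named gene or a list. As a random block (correlation 0.245) the experiment gave 27, 4, 3 and 9 at 6, 12, 18 h and 2 d, 392 at 3 d, 1921 at 4 d, 760 in the hour phase, 2769 between the phases, 3413 in uninfected leaves at 5 d minus 6 h, and 1794 and 3787 for the 2 tests of variation. At 24 h the random block gave 0, with 661 at an unadjusted p under 0.05 in limma without it.

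At 6 h no offset gave 1. At 2 d the count was 5 with the larger offset, 3 after quantile normalization and with the stricter filter, and 0 with no filter and without the trend, and at 18 h it was 2 after quantile normalization. The difference between experiments was found for 2 probe sets with the larger offset, quantile normalization, 75th percentile scaling or the stricter filter, and for 9 with RNA quality covariates. Those covariates gave 730 for uninfected leaves over time. Fitted to the arrays of a time alone, where fewer arrays estimate the spread, the counts were 0 at 6 h and 2 d, 196 at 4 d and 1785 at 5 d. Of the 5 list calls, 3 remained with the stricter filter, with RNA quality covariates and with an estimated correlation, each time the ER list, and fry, which asks whether a list's genes move one way, gave 9.

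Leaving out an experiment moved the counts to 0 to 1 at 6 h, 0 to 1 at 12 h, 0 to 2 at 18 h, 0 to 4 at 2 d, 28 to 59 at 3 d, 149 to 948 at 4 d, 874 to 2728 at 5 d, 1084 to 1774 over all times, 8 to 244 in the hour phase, 1623 to 2856 in the day phase, 247 to 1499 between the phases, 11 to 904 in uninfected leaves at 5 d minus 6 h, 60 to 628 for the variation of the response, 11 to 932 for uninfected leaves over time, 0 to 20 for the difference between experiments and 3 to 6 for the lists.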

Other observations

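The tests on gene families and on infected leaves over time were chosen after the data had been seen, as were the genes named here.

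Tau class glutathione transferase genes were lower in infected leaves in the day phase. GSTU26 fell by 1.05 ± 0.19 (log2, SE, 12 arrays per treatment), GSTU20 by 0.80 ± 0.09, GSTU16 by 0.45 ± 0.11 and GSTU27 by 0.36 ± 0.08, while GSTU23 (-0.28) and GSTU18 (-0.13) did not pass. With 4 of 6 falling, the family stood below other genes under all 3 scalings (median -0.40, camera adjusted p = 0.0032 over 38 families, and adjusted p = 0.0308 with an estimated correlation). Genes of the IQD family, whose proteins bind calmodulin, were also lower, with 5 of 9 falling and 4 of 9 under both other scalings (median -0.28, camera adjusted p = 0.0078, but adjusted p = 0.0884 with an estimated correlation). Examples were IQD22, which fell by 0.67 ± 0.16, and IQD30, which fell by 0.48 ± 0.08. RALFL34 and RALFL33, genes of small secreted peptides, fell by 0.60 ± 0.09 and 0.54 ± 0.14, but the family passed only in part (3 of 6 fell, camera adjusted p = 0.0381, after quantile normalization 0.0518, and adjusted p = 0.2944 with an estimated correlation).

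At 5 d, 3 of 5 beta-tubulin genes fell under all 3 scalings (median -0.82, camera adjusted p = 0.0132, but adjusted p = 0.2638 with an estimated correlation). In the day phase TUB6 fell by 0.37 ± 0.07 and TUB7 by 0.46 ± 0.15, while the family did not pass there under any of the 3 scalings (camera adjusted p = 0.0772, 0.0706 after quantile normalization and 0.0985 with 75th percentile scaling). Of the 6 glutamate receptor-like genes, GLR1.4 (0.89 ± 0.10), GLR2.7 (0.72 ± 0.10) and GLR2.8 (0.67 ± 0.19) rose in the day phase, the other 3 (GLR3.3, GLR3.5 and GLR3.6) did not pass, and the family did not differ from other genes (camera adjusted p = 0.1321). Of 5 WRKY genes WRKY47 (1.09 ± 0.14) and WRKY6 (0.76 ± 0.16) rose in the day phase, where the family did not differ from other genes (camera adjusted p = 0.1321), and 3 of 5 rose at 5 d under all 3 scalings (median 1.44, camera adjusted p = 0.0132, but adjusted p = 0.1256 with an estimated correlation). The 69 tested genes of the plastid genome had a median of 0.08 in the day phase and did not differ from other genes (camera adjusted p = 0.2791). At 4 d their median was 0.15 (camera adjusted p = 0.1016, and 0.0368 with the experiment as a block, but 0.7821 with an estimated correlation) and at 5 d it was -0.22, with 64 of 69 lower (camera adjusted p = 0.1492, and 0.0414 with the experiment as a block, but 0.8423 with an estimated correlation).

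From 6 h to 5 d, 4866 probe sets changed in infected leaves, 2360 higher and 2506 lower, against 1454 in uninfected leaves. This comparison joins the infection with the passage of time.

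The control probe set for 25S ribosomal RNA had an intensity under 100 on 6 of the 8 hour phase arrays of experiment 2, with 3 infected and 3 uninfected among them, on 3 of its 8 day phase arrays and on 1 day phase array of experiment 3. The median of the 8 hour phase arrays was 1589.6 in experiment 1, 34.3 in experiment 2 and 1682.4 in experiment 3. In the same arrays of experiment 2, 0 probe sets changed with infection in limma, with 1284 at an unadjusted p under 0.05.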
